A study of Mus musculus with 4 samples.

How the data were processed

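Total RNA from 4 mouse samples was labelled with biotin and hybridised to Affymetrix arrays, as given by the labels' protocols; the probe annotation used here is that of the Mouse Genome 430 2.0 array. Per the labels' protocols, MEF came from embryos and were grown in serum medium, reprogramming used retroviral vectors for Oct4, Sox2 and Klf4 with a stepwise change to stem cell medium with vitamin C, and ESC and iPSC were grown on irradiated MEF in medium with leukemia inhibitory factor. The labels give 4 groups with 1 array each, and each column was tied to its group by its sample label.

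The deposited values are probe set intensities made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects background, equalises the arrays and summarises the probes of a set, so differences near the floor are compressed and a global shift between arrays would be removed. The deposited intensity was found to be linear from its range, 2.96 to 20510, and log2 was taken here; no value was below the floor of 1. The quartiles of the 4 arrays were close, with 25th percentiles of 11.6 to 12.5 and 75th percentiles of 164 to 183. The scanner files were not used here, so detection calls were not made and an array's median served as the limit for dim probe sets.

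Of 45037 probe sets 34945 were paired with 1 gene by the annotation table, 932 with several and 9160 with none named here. The gene IDs of 34741 were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names, chromosomes and gene order alone, and no coordinates are given because no build is named for the array values. This left 18193 genes, of which 9010 had 2 or more probe sets; a gene takes the value of the probe set with the highest mean over the 4 arrays. No gene is named from a probe set with several genes, and genes whose bright probe sets disagree in sign are named only with that said.

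A probe set or gene counted as different when its log2 values differed by at least 1 and the higher one lay above the median of its array. The 5 comparisons, the 40 gene lists, the size rule and the rule for named genes were fixed before the data were examined; tests chosen later are named as such in the closing section. Each list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called beyond the limits below percentile 2.5 or above 97.5. This describes the arrays and is no test; 112 of the 200 list results were beyond the limits, where 10 would be by chance. Counts of list members cover those above the median on 1 of the 2 arrays, while medians cover all members measured. The order classes and slopes were set beside 100 simulations of unchanged arrays, with noise drawn from iPSC against ESC.

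Genes were named by a rule: in each comparison the 8 highest and 8 lowest genes that passed the size rule, leaving out provisional symbols; in each list up to 4 members with the widest and 2 with the smallest difference; in each order class the 6 widest; and Pou5f1, Sox2, Klf4, Nanog, Thy1, Col1a1, Cdh1, Snai2 and Xist throughout. The text prints a part of these.

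Alternatives were a 1.5-fold and a 3-fold rule, no filter, a filter at the 75th percentile, quantile normalization, centring on the array median, counting genes, leaving out probe sets that can cross-hybridise (_s_at, _x_at and _a_at), averaging all probe sets of a gene, the probe set with the widest spread, other selections for the slopes and Spearman correlation. Leaving out chromosomes 11 and X, or Mycn, was added after seeing the data. The scripts were tested on simulated data. Of 200 probe sets changed 4-fold in a simulated OSK day 7 against MEF over 45037 probe sets, 200 were recovered with 0 false calls. Of 200 changed 1.41-fold, under the size rule, 3 were called. The noise in this simulation was far narrower than 2-fold and only bright probe sets were changed. It therefore checks the code, and its 0 false calls give no error rate for these arrays. With noise drawn from iPSC against ESC, 12 of 200 random lists of 20 genes over 18193 genes were called in a simulated iPSC against MEF without change. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.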

Results

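Gene expression was measured on 4 oligonucleotide arrays that follow mouse fibroblasts on their way to induced pluripotent stem cells. The groups were embryonic fibroblasts (MEF), MEF 7 days after retroviruses carrying Oct4, Sox2 and Klf4 had been added (OSK day 7), induced pluripotent stem cells (iPSC) and embryonic stem cells (ESC), all of the C57BL6 strain. Each group had 1 array, so no difference below has a replicate check and no p-value is given; the number of arrays limits the precision. Differences are on the log2 scale, 1 unit being 2-fold, and a probe set or gene is called higher or lower only when it differed by at least 2-fold and its brighter value lay above that array's median. The 45037 probe sets had median intensities from 36.9 in iPSC to 38.5 at OSK day 7. Probe sets of the same gene varied with an SD of 0.43 to 0.64 in the 5 comparisons, which covers differences between probes and not between cultures.

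Across 26492 probe sets above the array median on at least 1 array, the iPSC and ESC arrays were the most alike, with a Pearson correlation of 0.938, followed by MEF and OSK day 7 at 0.913. MEF correlated with ESC at 0.804 and with iPSC at 0.759. The OSK day 7 array lay farther from both pluripotent arrays than MEF did, with 0.743 against ESC and 0.69 against iPSC. These correlations run across probe sets, which are not independent replicates. In the 5 comparisons counted, the number of probe sets at least 2-fold apart ran from 3367 between iPSC and ESC and 3828 between OSK day 7 and MEF to 10839 between iPSC and OSK day 7.

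**Figure D1:**
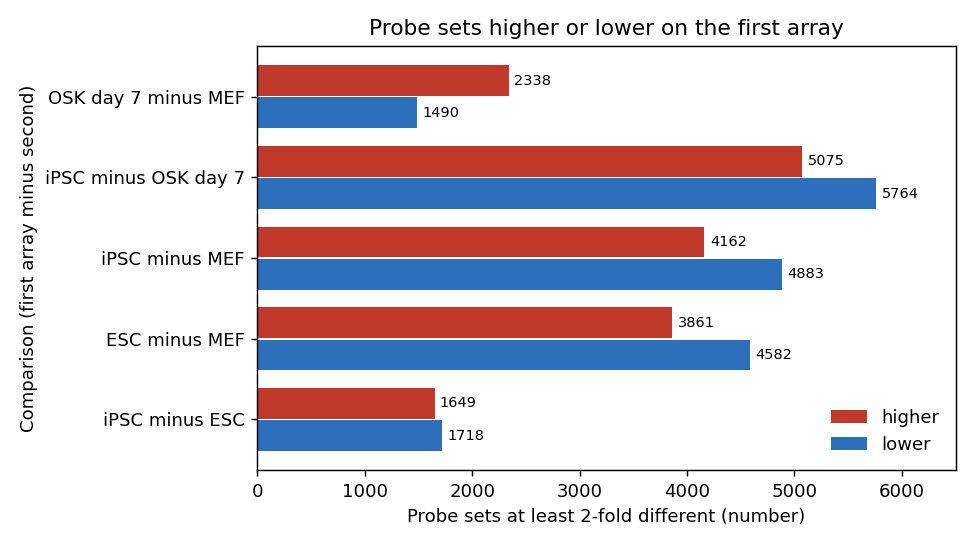
Number of probe sets at least 2-fold higher (red) or lower (blue) on the first array of each comparison, with 1 array per group. The OSK day 7 array differed from MEF by 2338 higher and 1490 lower probe sets, and iPSC from OSK day 7 by 5075 and 5764.

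The comparison of OSK day 7 with MEF asks what had changed in the culture 7 days after the factors were delivered. Interferon and antiviral genes were higher, muscle and macrophage genes were lower, and a part of the pluripotency and epithelial genes were higher, while 9 of 37 fibroblast and matrix genes were higher and 2 lower. Of 24 antiviral genes above the array median, 21 were at least 2-fold higher and none lower, with a list median of 2.34. Ifit1 was higher by 4.92, Oasl2 by 4.45 and Ifit3 by 4.26, all of them interferon-induced genes that act against viral RNA. Irf1 differed by 0.31. In all, 2338 probe sets were higher and 1490 lower, or 15.9% of the 24073 above the median.

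Pluripotency genes formed a mixed group at day 7. Of 28 members above the median 18 were higher and 1 lower, and the list median of 0.63 lay above all of 10000 random lists. Tfcp2l1, a transcription factor of naive pluripotency, was higher by 5.44, L1td1 by 5.33, Fbxo15 by 4.46 and Nanog by 3.35. Pou5f1, which encodes Oct4, went from 3.67 in MEF to 6.04, a difference of 2.37. Sox2 stood at 5.11 on both arrays and Klf4 at 9.41 and 9.66. Whether the probe sets of these 3 genes read the delivered transcripts as well as the cells' own is not given in the sources used here. Mycn had a probe set that was higher by 8.26, but its other probe sets differed by 0.27 and 0.91, so the gene has no settled value at day 7. Among the early reprogramming markers 7 of 10 were higher, with a list median of 1.3. The 7 include Mycn and Epcam, whose other probe sets were within 2-fold. The list kept its call without Mycn, which was left out after seeing the data.

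Epithelial genes went in both directions. Epcam had probe sets at 4.29 and 0.37, so only the one was beyond 2-fold; Cdh1, the gene of E-cadherin, was higher by 3.75 and the protease gene St14 by 2.91, whereas the keratin gene Krt18 differed by -2.75. The count was 7 higher and 2 lower of 18, and the list median of 0.16 lay at percentile 97.8, just beyond the limit; it lost that call at 0.07 without probe sets that can cross-hybridise. The mesenchymal transition factors had 2 higher and 4 lower of 16 and a median of 0.02, within the random lists. Twist2 differed by -1.51, Snai1 by -1.44 and Tgfb1 by -1.42, while Snai2 stood at -0.99, with its other probe set at -1.16.

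The fibroblast and extracellular matrix list had 9 of 37 members higher and 2 lower, with a median of 0.39. The proteoglycan genes Lum and Dcn were higher by 3.91 and 3.55, and the matrix metalloproteinase gene Mmp3 by 2.95. Nt5e had probe sets at 3.58 and 0.18. Col1a1 differed by 0.55 and the surface antigen gene Thy1 by -0.9. The TGF-beta responsive list was lower, with a median of -0.47 and 3 of 12 members lower, among them Inhba at -1.76 and Tnc at -1.37, with another Tnc probe set at -0.13; Tgfbi was higher by 1.24. This list lost its call at -0.32 without probe sets that can cross-hybridise.

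All 13 muscle genes above the median were lower, with a list median of -3.62. The cardiac actin gene Actc1 fell from 10.7 to 4.59, and Myh3, Myl1 and the myogenic regulator Myog differed by -4.8, -4.61 and -4.47. Of 13 macrophage genes 11 were lower, including the complement genes C1qb at -3.19 and C1qa at -2.68 and the pan-leukocyte gene Ptprc at -2.95. In the endothelial list 4 of 8 were lower and 2 higher, with Emcn at -3.58 and Tek at 5.8. Markers of these other cell types thus moved with the comparison, beside the matrix and metabolic genes.

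Several metabolic lists were lower at day 7. In the serine, glycine and one-carbon list 6 of 9 members were lower with a median of -1.4, among them the mitochondrial folate enzyme gene Mthfd2 at -3.45, Phgdh at -2.19, Psat1 at -2.17 and Shmt2 at -2.03. Glycolysis had 9 of 17 lower and 2 higher, with a median of -1.03; the glucose transporter gene Slc2a1 differed by -2.55, the lactate transporter gene Slc16a3 by -2.19 and Aldoc by 2.01. Cholesterol synthesis had 4 of 14 lower, with Fdps at -1.34 and Lss at -1.7, where the Lss probe sets ran up to -0.87. In the heat shock and stress list 5 of 20 were lower and 1 higher. The lower ones were Trib3 at -4.29, Chac1 at -3.68, Asns at -2.54, Ddit3 at -2.4 and Atf4 at -1.2, and the higher one was Egr1 at 1.24, where Atf4 and Egr1 were named after their values were seen and other Atf4 probe sets stood at -0.7 and -0.17. None of the 33 cell cycle genes differed by 2-fold, the widest being Cdt1 at -0.71.

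The highest differences outside these lists were Crym, a thyroid hormone binding protein gene, at 8.28 (310-fold), Aldh3a1 at 7.19, Sbspon at 7.0, the matrix gene Prelp at 6.53, Fmo1 at 6.43 and the skeletal myosin gene Myh1 at 6.28. The chemokine gene Cxcl5 was higher by 6.08 and Saa3 by 5.69, and 4 of 14 inflammatory genes were higher against 1 lower. The bone matrix gene Ibsp fell by 5.56 on the log2 scale, from 8.85 to 3.29. The Wnt list had 4 of 15 members higher and 1 lower, led by Sfrp2 at 2.8. The p53 and senescence list had 6 of 19 higher and 2 lower, led by Igfbp3 at 2.98, with Cdkn2a at 1.54. Medium, virus exposure and time changed together with the factors between these arrays, so the comparison does not separate them.

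**Figure D2:**
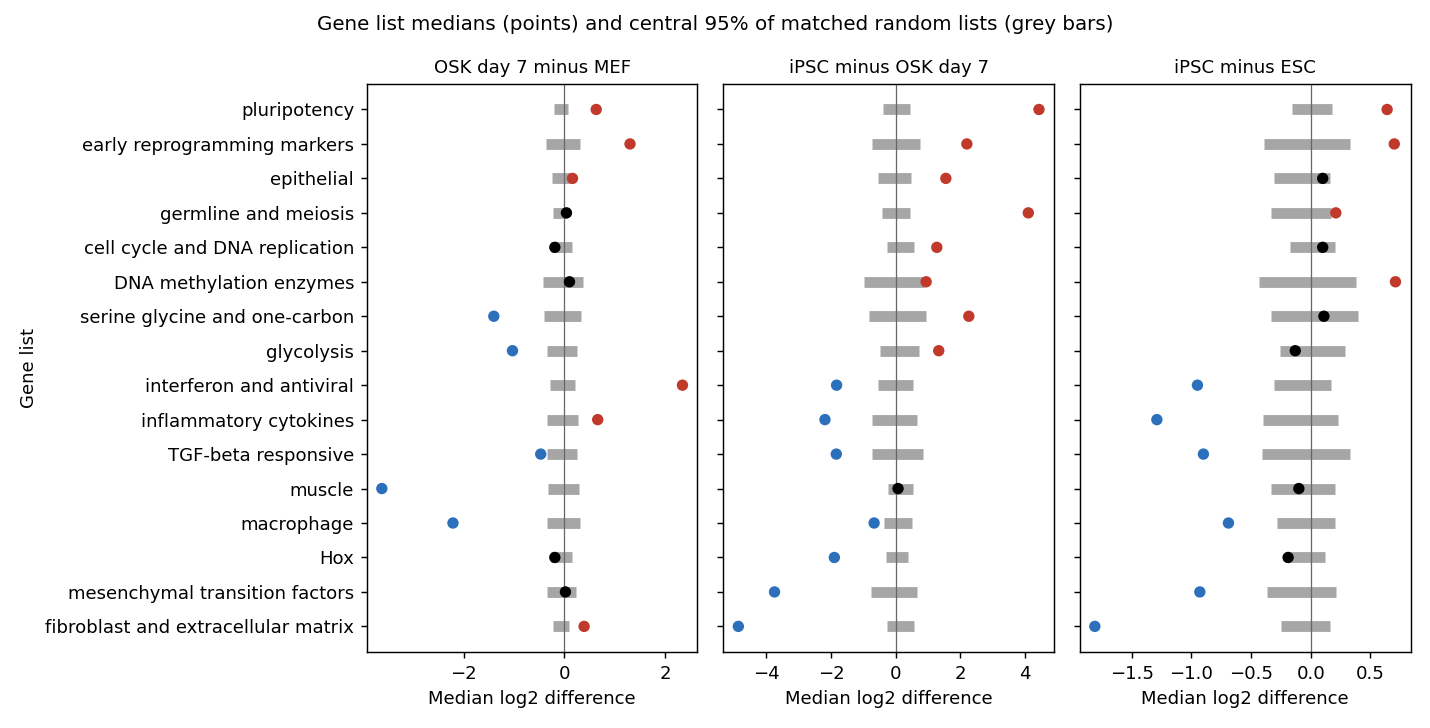
Median log2 difference of 16 gene lists (points) in 3 comparisons, with the central 95% of 10000 random lists matched on mean expression (grey bars); red points lie above that range, blue below and black within it. The antiviral list stood at 2.34 at OSK day 7 against MEF and at -1.83 in iPSC against OSK day 7, while the pluripotency list went from 0.63 to 4.43.

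The comparison of iPSC with OSK day 7 asks what separates the intermediate culture from established pluripotent cells. Pluripotency and germline genes were higher almost without exception, and matrix, mesenchymal and Hox genes were lower. Of 45 pluripotency genes 42 were higher and 1 lower, with a list median of 4.43. Dppa2 was higher by 9.15, Zfp42 (Rex1) by 7.65, the Nodal co-receptor gene Tdgf1 by 7.59, Sox2 by 7.14, Pou5f1 by 5.81, Nanog by 5.59 and Klf4 by 1.99. The lower member was Mycn at -5.78, whose other probe sets were higher by 5.01 and 1.45; Cd9 differed by -0.21. All 37 fibroblast and matrix genes were lower, with a median of -4.87, from Lum at -7.03 and Fbln5 at -7.0 to Tagln at -2.23. In total 5075 probe sets were higher and 5764 lower, or 42.6% of 25419.

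Of the mesenchymal transition factors 14 of 15 were lower, with a median of -3.75; Cdh11 differed by -6.36, Tgfbr2 by -5.44, Prrx1 by -5.36 and Snai2 by -4.14. Epithelial genes were higher in 14 of 23 cases and lower in none, led by the splicing regulator gene Esrp1 at 5.16, the claudin gene Cldn4 at 3.75 and Cdh1 at 3.37. Of 20 germline and meiosis genes 19 were higher, with Rhox5 at 8.13, Dazl, which encodes an RNA-binding protein of germ cells, at 7.79 and Stra8 at 6.64. The Hox list had 21 of 23 lower, with Hoxc8 at -6.01 and Hoxa9 at -5.0, and 16 of 18 mesoderm and limb factors were lower, with Foxd1 at -6.23.

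Cell cycle and replication genes were higher in 27 of 33 cases and lower in none, with a median of 1.27. Cdc6 and Cdt1, which license replication origins, were higher by 3.04 and 2.73 and Mcm3 by 2.52, while Mki67 differed by -0.28. All 10 genes of the serine, glycine and one-carbon list were higher, from the glycine cleavage gene Gldc at 4.6 to Phgdh at 1.37. Glycolysis had 12 of 17 higher and 1 lower, with Slc2a1 at 4.16 and Hk2 at 2.66. Of 11 DNA methylation enzyme genes 5 were higher and 1 lower, with Dnmt3l at 6.07, Dnmt3b at 5.09 and Tet1 at 4.05. Among 50 histone and chromatin regulators 21 were higher and 6 lower; the Polycomb gene Cbx7 differed by 3.78 and the remodeller gene Smarca2 by -4.24.

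Antiviral genes went the other way from the first step. Of 24 members 17 were lower and none higher, with Ifit1 at -5.95 and Ifit3 at -4.73, and 11 of 13 inflammatory genes were lower, with Cxcl5 at -7.32. The p53 and senescence list had 11 of 19 lower and 3 higher, with Igfbp3 at -6.24 and the cell cycle inhibitor genes Cdkn1c at -5.11 and Cdkn2b at -3.27. The TGF-beta responsive list had 8 of 12 lower and 2 higher, with Tgfbi at -5.87 and Thbs1 at -5.25. Outside the lists, genes among the lowest were Ccn3 at -8.37, Fmod at -8.34, Ecrg4 at -8.21, Crym at -8.17, Sbspon at -7.99 and Agtr2 at -7.78, and the highest were Trap1a at 9.09 and Mageb16 at 8.1. The median difference over all probe sets was 0.14 here, against which the list medians are to be read.

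The comparison of iPSC with MEF sets the product beside the starting cell type. The cultures also differed in medium and feeder cells, which the comparison does not separate, and in Y-linked genes, given below. All 45 pluripotency genes above the median were higher, with a median of 5.78, and 36 of 37 fibroblast and matrix genes were lower, with a median of -4.48. Dppa5a was higher by 9.92 (968-fold), Tdgf1 by 9.08, Nanog by 8.95, Fbxo15 by 8.78, Pou5f1 by 8.18, Sox2 by 7.14 and Klf4 by 2.24. Fbln5 differed by -6.23, the collagen gene Col12a1 by -6.18, Postn by -5.7 and Col1a1 by -4.44, and the exception was Mmp3 at 0.41. Epithelial genes were higher in 15 of 23 cases and lower in 2, with Cdh1 at 7.12 and Epcam at 7.31, where the other Epcam probe set stood at 0.56, and 15 of 16 mesenchymal factors were lower, with Snai2 at -5.13.

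Of 33 cell cycle genes 23 were higher, of 20 germline genes 19 and of 11 DNA methylation enzyme genes 6. Muscle genes were lower in 12 of 13 cases, with Actc1 at -6.04 and Cnn1 at -5.37 and Mylpf higher by 1.58. Of 13 macrophage genes 10 were lower and 1 higher, with the lysozyme gene Lyz2 at -4.85 and the receptor gene Csf1r at -4.02, its probe sets running up to -0.69. The antiviral list had a median of 0.31, within the random lists, with 9 of 20 members higher and 3 lower; Ifitm1 differed by 3.18 and Ifit2 by -3.33, and the list passed the limit at 0.4 after quantile normalization. Glycolysis, with a median of 0.21, and the serine and one-carbon list, with 0.59, lay within the random lists as well. The lowest genes were Epha3 at -6.57, Col11a1 at -6.53, the smooth muscle actin gene Actg2 at -6.47 and Ibsp at -6.41. The counts were 4162 probe sets higher and 4883 lower.

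**Figure D3:**
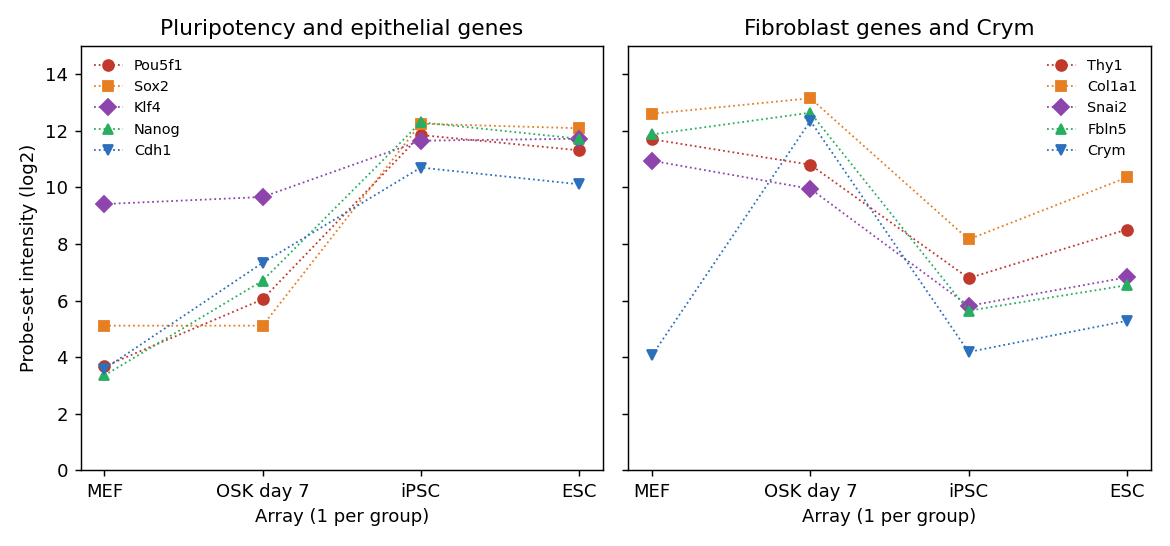
Log2 intensity of 10 genes on the 4 arrays (1 array per group; dotted lines only join the points of a gene). Nanog stood at 3.35, 6.7, 12.3 and 11.72 in MEF, OSK day 7, iPSC and ESC, Col1a1 at 12.6, 13.15, 8.16 and 10.35, and Crym at 4.07, 12.35, 4.18 and 5.28.

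The comparison of ESC with MEF served as the reference distance. It gave 3861 probe sets higher and 4582 lower in ESC. Of 45 pluripotency genes 43 were higher, with a median of 4.6, led by Dppa5a at 9.7, Zfp42 at 9.19, Tdgf1 at 8.9 and Nanog at 8.37; Cd9 differed by 0.5. Of 37 fibroblast and matrix genes 34 were lower and 1 higher, with a median of -2.66, with Fbln5 at -5.34 and Col12a1 at -4.68. Lum at -0.6 and Dcn at 0.01 were within 2-fold, and the higher member, named after its value was seen, was Mmp3 at 2.31. Mesenchymal factors were lower in 14 of 16 cases, epithelial genes higher in 14 of 23 and lower in 2, and germline genes higher in 18 of 19. The antiviral list was higher in ESC than in MEF, with 15 of 23 members higher and 1 lower and a median of 1.72, among them Oas2 at 3.96 and Oas1a at 3.64. The LIF and STAT3 list had 6 of 12 higher and 2 lower, with Gbx2 at 4.46 and the feedback inhibitor gene Socs3 at 3.0. Cholesterol synthesis had 8 of 14 lower, with Fdps at -1.8 and Sc5d at -2.26, whose probe sets ran up to -0.8, and muscle genes were lower in all 13 cases.

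Over the 8443 probe sets that differed between ESC and MEF, the iPSC array covered 97.2% of the difference by the slope through 0, and the OSK day 7 array 9.45%, with medians over the probe sets of 94.8% and 4.71%. With the probe sets chosen by iPSC against MEF the slopes were 111% and 8.46% and the medians 125% and 3.5%. Both slopes use the MEF array that also enters the reference difference. Simulated arrays without any change gave 49.9%, which holds for probe sets chosen by noise alone and is no level to set these values against. Of the 3861 probe sets higher in ESC, 13.1% were at least 2-fold higher at day 7 and 64.5% in iPSC. Of the 4582 lower in ESC, 642 were lower at day 7 and 3606 in iPSC, or 78.7%, while 10.9% were at least 2-fold higher at day 7. Beside these day 7 shares stand 2338 higher and 1490 lower probe sets among all 24073 above the median in OSK day 7 against MEF. The differences from MEF correlated between iPSC and ESC at 0.85, with a covariance of 1.0 against 0.19 in the simulation, and between OSK day 7 and ESC at 0.13, with a covariance of 0.09 against 0.19. In both iPSC and ESC 2429 probe sets were higher than in MEF, where independent lists would share 553 and the simulation gave 556. Part of the excess may come from the shared MEF array. OSK day 7 and ESC shared 476 higher and 642 lower probe sets. Independent lists would share 214 and 295, and the simulation gave 553 and 671. The day 7 overlap was thus no larger than in simulated arrays that share MEF.

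The order of change was read from MEF, OSK day 7 and iPSC. Each array reads a whole culture, so late names a class and not the time of change within cells. The iPSC were also grown on irradiated MEF in medium with leukemia inhibitory factor, which these arrays do not separate from time. Late change was the most frequent pattern, with 2893 probe sets higher and 3091 lower between day 7 and iPSC after less than 2-fold change before, against medians of 627 and 547 in simulated arrays without change. Dppa2, Trap1a, Mageb16, Dazl and Zfp42 led the late rise, and Epha3, Fbln5, Col11a1, the fibrillin gene Fbn2 and Igfbp5 the late fall; Fbln5 stood at 11.87, 12.64 and 5.64 on the 3 arrays. Higher at both steps were 152 probe sets, against 24 simulated, and they included Dppa5a at 3.9, 6.7 and 13.82, Nanog, Fbxo15, Pou5f1 and Eras. Lower at both steps were 218, against 25, with Actg2, Tgfb3, Filip1l and Ankrd1, which stood at 10.72, 7.32 and 4.69.

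Another pattern was a passing change at day 7. It held 1729 probe sets that were higher at day 7 alone, against 680 simulated, with Crym, Sbspon, Prelp, Aldh3a1, Fmo1 and Myh1 in front. Lower at day 7 alone were 677, against 596, with Trib3 at 9.6, 5.31 and 9.53 in MEF, OSK day 7 and iPSC, Chac1 at 8.91, 5.22 and 9.2 and Mthfd2 at 10.74, 7.3 and 10.29. Early change that was kept was less frequent than in the simulation, with 274 higher against 548 and 409 lower against 621. The leading genes of the early and kept class lay far above 2-fold, with Fgfbp1 higher by 4.06 and Ifitm1 by 3.99 at day 7 and Actc1 at -6.11, although Actc1 stood at 9.57 in ESC. The simulated noise was drawn from iPSC against ESC, which hold real differences, and the noise between MEF and day 7 arrays was not measured.

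**Figure D4:**
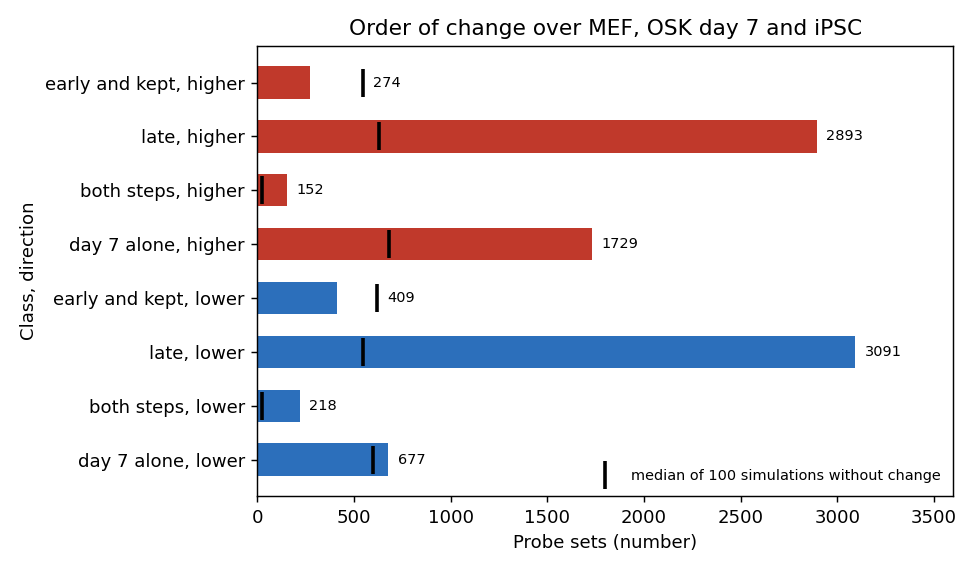
Probe sets in each class of change over MEF, OSK day 7 and iPSC (bars; red higher, blue lower; 1 array per group), with the median of 100 simulations without change (black marks). The late classes, at 2893 and 3091, and day 7 alone higher, at 1729, exceed their marks. Both early and kept classes, at 274 and 409, fall short of theirs, for which the simulation without change is no fair level.

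The comparison of iPSC with ESC asks how closely the product resembled embryo-derived cells. Pou5f1, Sox2 and Nanog were within 2-fold, and matrix, inflammatory and antiviral genes were lower in iPSC. Pou5f1 differed by 0.55, Sox2 by 0.17 and Nanog by 0.57. The Klf4 probe set with the higher mean over the arrays differed by -0.07 and its other probe set by -1.2, beyond 2-fold. The pluripotency list as a whole was higher in iPSC, with a median of 0.64 and 10 of 45 members higher against 2 lower. Tcl1 differed by 3.71, Dppa3 (Stella) by 2.85 and Lin28a by 2.35. Of the 2 lower members 1 was Zfp42 (Rex1), at 9.97 in iPSC and 11.83 in ESC. The fibroblast and matrix list was lower in 29 of 36 cases and higher in none, with a median of -1.81, including Col6a1 at -3.14, the receptor gene Pdgfrb at -3.1, Postn at -2.91, Col1a1 at -2.19 and Thy1 at -1.72. Both cultures were grown on irradiated MEF feeder cells, and these arrays do not separate feeder from stem cell transcripts.

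Of 23 antiviral genes 11 were lower in iPSC, with Ifit1 at -3.56 and Oas2 at -2.49, and of 14 inflammatory genes 9, with Il6 at -3.27 and Ccl5 at -2.1. Macrophage markers moved with them: their list had a median of -0.69, with 4 of 8 members lower and 1 higher, among them Lyz2 at -2.8, which stood at 4.77 in iPSC and 7.57 in ESC, and Cd68 at -1.6. Its other lower members were Fcer1g at -1.36 and C1qa at -1.13, the latter named after its value was seen, and the higher one was Mrc1 at 1.36. The LIF and STAT3 list was lower with a median of -0.6, including Stat3 at -1.74 and Socs3 at -1.57, and the TGF-beta responsive list with -0.9, including Inhba at -2.51. DNA methylation enzyme genes were higher in 4 of 11 cases and lower in 1, with a median of 0.71 that lost its call at 0.27 with the probe set of widest spread, and Dnmt3l differed by 2.58, Dnmt3b by 1.76 and Tet1 by 1.26. Epithelial genes had a median of 0.1, within the random lists, though Esrp1 was higher by 4.08 and Cldn4 by 3.03 and Dsp lower at -2.16. Cell cycle genes had 3 of 33 higher and none lower. The highest genes were Mcf2 at 6.49, the oligodendrocyte lineage genes Olig1 and Olig2 at 5.4 and 4.32 and Hesx1 at 4.1. Among the lowest were Kbtbd11 at -6.55, Actc1 at -4.91, the interferon-induced GTPase gene Gbp2b at -4.8, Cubn at -4.22 and Lama1 at -3.56. Egr3 stood at -4.09, but its probe sets disagreed in sign and ran up to 0.0.

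Shifts by chromosome accompanied this comparison. The 386 X-linked genes above the array median had a median of 0.68, and the 1002 genes of chromosome 11 one of -0.47, whereas the other autosomes lay between -0.16 and 0.03. Without the genes of these 2 chromosomes, a set chosen after seeing the data, each count involving ESC stayed within 1.5 times its value. They hold a small part of the 11663 genes above the median in iPSC against ESC, so this was likely in advance. It does not show that they add little. On chromosome 11, 787 of the 1002 genes were within 2-fold, and on the X 251 of the 386. All 4 samples are labelled male, yet the Y-linked genes Eif2s3y and Kdm5d stood at 7.54 and 6.64 in MEF and at 3.31 and 2.94 in iPSC and 4.55 and 3.12 in ESC. Xist, the RNA of the inactive X, was at 11.22 in MEF, 11.11 at day 7, 9.18 in iPSC and 9.28 in ESC. Its other probe sets stood at 9.83, 9.7, 6.16 and 6.88 and at 9.38, 9.21, 6.18 and 6.29 in the same order, so that iPSC differed from MEF by -2.04, -3.66 and -3.2.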

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

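Leaving out Mycn and leaving out chromosomes 11 and X were chosen after seeing the data; all other alternatives were fixed before. The 10 counts of probe sets stayed within 1.5 times their value without a filter, after quantile normalization, after centring the arrays and without probe sets ending in _s_at, _x_at or _a_at. So did the 4 counts run without chromosomes 11 and X, which was likely in advance for so small a part of the genes. No replicate could be left out with 1 array per group. Of 200 list medians 2 lost and 3 gained their call after quantile normalization, and no list beyond the limits turned its sign. The call was kept by 194 with the mean over probe sets and by 193 with the probe set of widest spread. Without _s_at, _x_at and _a_at probe sets 180 kept it. Of 196 over members above the median 184 kept it, of 80 without chromosomes 11 and X 78 and of 10 without Mycn 10. Of those 80, glycolysis in ESC against MEF lost its call at 0.45 and germline and meiosis in iPSC against ESC at 0.16. Of 1160 named gene values 1146 stayed on the same side of 2-fold after quantile normalization and 1107 with the mean over probe sets. The sign was compared only for lists beyond the limits and for genes at least 2-fold apart. The dimmer array value of many named genes lies near the floor, which limits the size of their differences.

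At 1.5-fold the counts beyond 1.5 times their value were 4296 higher and 3912 lower for OSK day 7 against MEF, 8097 higher for iPSC against OSK day 7, 7188 higher for iPSC against MEF, 6917 higher for ESC against MEF and 3825 higher and 4142 lower for iPSC against ESC. At 3-fold they were 1142 higher and 432 lower for OSK day 7 against MEF, 2417 higher and 3831 lower for iPSC against OSK day 7, 1909 higher and 3011 lower for iPSC against MEF, 1695 higher and 2559 lower for ESC against MEF and 564 higher and 552 lower for iPSC against ESC. With the filter at the 75th percentile they were 1249 higher and 874 lower for OSK day 7 against MEF, 3539 lower for iPSC against OSK day 7, 2575 higher and 2938 lower for iPSC against MEF, 2291 higher and 2818 lower for ESC against MEF and 970 higher and 875 lower for iPSC against ESC. Counted as genes they were 1167 higher and 723 lower for OSK day 7 against MEF, 2430 higher and 2998 lower for iPSC against OSK day 7, 1930 higher and 2593 lower for iPSC against MEF, 1837 higher and 2325 lower for ESC against MEF and 716 higher and 922 lower for iPSC against ESC. These shifts follow from the stricter or looser rule and from counting fewer units.

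At 3-fold the order of change gave 126 higher and 194 lower early and kept, 1351 higher late, 43 higher and 36 lower at both steps and 842 higher and 116 lower at day 7 alone. As genes it gave 136 higher and 208 lower early and kept, 1376 higher and 1651 lower late, 90 higher and 128 lower at both steps and 858 higher and 305 lower at day 7 alone.

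The percentage of the MEF to ESC difference covered at day 7 was 10.1 with a 3-fold choice, 8.46 when chosen by iPSC and 9.43 without a filter, and for iPSC 98.3, 111 and 96.7. Spearman correlations were 0.901 for MEF and OSK day 7, 0.737 for MEF and iPSC, 0.785 for MEF and ESC, 0.671 for OSK day 7 and iPSC, 0.727 for OSK day 7 and ESC and 0.923 for iPSC and ESC. Over all probe sets Pearson correlations were 0.961 for MEF and OSK day 7, 0.895 for MEF and iPSC, 0.915 for MEF and ESC, 0.867 for OSK day 7 and iPSC, 0.891 for OSK day 7 and ESC and 0.97 for iPSC and ESC. Both kept the order of the 6 pairs.

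The epithelial list at day 7 against MEF had a median of 0.07 without _s_at, _x_at and _a_at probe sets and was no longer beyond its random lists, and the antiviral list in iPSC against MEF passed them at 0.4 after quantile normalization. Among lists beyond the limits and named genes at least 2-fold apart, signs turned in 4 cases. Sign changes of smaller differences were not counted. The adipocyte and cartilage list in iPSC against OSK day 7 had 0.31 without _s_at, _x_at and _a_at probe sets, and with the mean over probe sets Mycn had 0.23 in iPSC against OSK day 7, Xiap 0.2 in ESC against MEF and Shmt1 -0.02 in iPSC against ESC. The probe sets of these 3 genes disagree in sign there, from -5.78 to 5.01 for Mycn, -1.07 to 0.82 for Xiap and -0.84 to 1.01 for Shmt1, so that their mean depends on the probe sets averaged; for the lists the cause was not tested.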

Other observations

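Gene groups outside the main account also moved. The imprinted Dlk1-Dio3 genes were lower in iPSC than in MEF, with a median of -2.43 and 4 of 4 members lower, and lower in ESC, with -1.89, a call lost at -1.03 without _s_at, _x_at and _a_at probe sets. Dlk1 differed from MEF by -3.88 in iPSC and -3.31 in ESC, and Meg3 by -2.34 and -1.03, its probe sets in ESC running from -2.83 to -0.23. Among other imprinted genes 13 of 17 were lower and 1 higher in iPSC than in MEF, including the growth factor gene Igf2 at -4.47 and Cdkn1c at -3.65, with Phlda2 higher by 3.61. The trophoblast list had a median of 0.68 in iPSC against ESC and 4 of 8 members higher, led by the X-linked homeobox genes Rhox6 at 3.31 and Rhox9 at 3.28, where X-linked genes as a whole had the same median of 0.68; without chromosomes 11 and X, chosen after seeing the data, the list kept its call at 0.79. Of the 2-cell-like list 7 members were measured and 6 are unnamed here; its median was 0.49 in the same comparison, 1 of 3 members above the array median was higher, Tcstv1 at 3.3, and the call was lost over those 3. The lysosome and autophagy list was lower in iPSC than in MEF, with a median of -1.0 and 10 of 20 members lower, a call lost at -0.24 without _s_at, _x_at and _a_at probe sets, among them the cathepsin genes Ctsk at -3.46 and Ctsb at -2.15, whose probe sets ran up to -0.84; Ulk1 was higher by 2.69. Ribosomal protein genes kept to 0.07 in iPSC and in ESC against MEF, within the random lists.

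The tests of matched lists, of the percentage of genes above 0, of Y-linked genes, of the X median and of the fibroblast genes were chosen after their results were seen; those of stretches were chosen after the pattern but before their own result.

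The ESC array read chromosome 11 higher as a whole: its 1002 genes had a median of -0.47 in iPSC against ESC, and its genes had a median of 0.45 in ESC against MEF. Normalization by intensity is argued against, since that median lay at percentile 0 of random lists matched on mean expression, and so are a few strongly changed genes, since 20.1% of its genes were above 0, where the other autosomes went no lower than 38.5%. A candidate explanation is extra copies of chromosome 11 in part of the ESC culture: in 10 of 10 stretches of its gene order the median was lower than that of any other whole autosome. No DNA was measured here, so the copy number itself is open, as are shared regulation of the chromosome and another difference between the cell lines.

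The Y-linked genes Eif2s3y, Kdm5d and Uty were at 3.31, 2.94 and 3.04 in iPSC and 4.55, 3.12 and 2.91 in ESC, with 0 of these 6 values above the array median, while Eif2s3y and Kdm5d were above it in MEF and at day 7. Uty tells little here, since it stood at 5.13 in MEF, under that array's median of 5.21, and at 5.49 at day 7. The low Eif2s3y and Kdm5d values are what cultures without a Y chromosome in most cells would give. The iPSC and ESC cultures may be female or have lost the Y, in spite of the label male. Low expression of an intact Y is not excluded. The X-linked genes had a median of 0.68 in iPSC against ESC, above every autosome, which argues against the same number of active X chromosomes in both, and 10 of 10 stretches of the X lay above the autosomes, which argues against a single cluster. Against MEF the X-linked median was 0.43 in iPSC and -0.25 in ESC. The 2 cultures thus lay on opposite sides of MEF, and the account of the low Y-linked genes need not be the same for both. Xist was high on the MEF and day 7 arrays beside the Y-linked genes, as a mixture of embryos of both sexes could give, which was not tested.

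Fibroblast genes were higher in ESC than in iPSC, and that list's median of -1.81 lay at percentile 0 of random lists matched on mean expression, which argues against normalization by intensity. If cells with the MEF profile were the source, the excess in ESC over iPSC would be a like percentage of the MEF intensity for all abundant MEF genes, with a ratio of its 75th to its 25th percentile under 2. The genes used were also at least 8-fold higher in MEF than in iPSC, so the iPSC value entered both their choice and the excess. Over 489 such genes above the 75th percentile of MEF the ratio was 4.42. The limit was then raised to the 90th percentile, with 4.42 already seen. Over the 265 genes left the ratio was 3.83 (95% interval from resampling genes, 3.2 to 5.16), with 29 of them under 1% and 21 over 20%. These values go against a uniform MEF profile, but the interval spans 4, the value set as the bound. Of 169 genes bright enough to tell, 7 had a whole ESC intensity under 3.1% of MEF, or 4.14% (exact binomial 95% interval 1.68 to 8.35). Both intervals treat genes read on 1 array per group as independent units and do not cover the spread between cultures. For genes at the median excess the spread between probe sets alone would give 5.06%. The limit was set 2 times below the median excess of these same genes, near the 25th percentile of 2.92%. The whole ESC intensity also holds the stem cells' own transcripts. A low count was thus likely in any case and does not decide the question. MEF-like cells as a part or the whole of the source therefore cannot be told apart from feeders of another profile or differentiating cells, which were not tested.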
